A study of Mus musculus with 9 samples.

How the data were processed

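The deposited data were raw read counts per gene and cell, with a cell type label for each cell. The table held 46517 gene rows and 1235 cells. Of these rows, 28386 had at least 1 read, 0 named no gene, and 42052 (90.4%) matched a symbol of the reference gene names. Symbols are printed as in the table, so that Plpp1, Plpp3, Gucy1a1, Gucy1b1 and Ccn1 appear under their older names Ppap2a, Ppap2b, Gucy1a3, Gucy1b3 and Cyr61. The values were whole numbers and the total per cell differed several-fold between cells, which is how raw counts look. Per the submitters' processing notes, SAMtools 1.16.1, featureCounts and Subread 1.4.6-p5 were used, and the builds GRCm38 and GRCm39 were named without the role of each. Every cell held at least 100021 reads, so cells of low depth had been removed before the deposit. The protocol was Smart-seq2, which reads whole transcripts and carries no molecular identifiers.

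Each cell took its type from the deposited label, and 0 cells lacked one. The label of the plate came from the prefix of the cell's name. All 1235 cells were kept. 0 columns of the count table were left out, and 0 cells had counts identical to those of another cell. No doublet caller was run; an alternative instead left out cells with markers of another class of cell.

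Counts were summed over the cells of a type and scaled to counts per 1000000 reads of that type (CPM). Differences are on log2(CPM + 5). Where a group joined several types, the group's value was the mean of the CPM of its types, so that capilEC did not dominate. The 3 endothelial types of the mean were aEC, capilEC and vEC, and the 3 mural types were PC, aSMC and vSMC. Each sum has an exact Poisson 95% interval and each share of cells an exact binomial (Clopper-Pearson) 95% interval, and a count of 0 was given the limit of 3 counts. For the shares of cells with a read that are printed with an interval, each cell was thinned at random to 100000 reads, so that depth did not differ between types.

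A gene met the size rule when it had at least 50 CPM in the higher group, a read in at least 50% of that group's cells, and at least a 4-fold difference (2 log2 units). For a group that joined types, the share of cells was the mean of its types. The share in this rule was taken on all reads of each cell without thinning, so it depends on depth. Values by plate were computed where a plate held at least 5 cells of each compared type. The genes named are the first 12 in each direction, ranked by log2 difference, among those that met the size rule with the same direction in every such plate. For each type against all others, the first 6 genes at least 4-fold above the second-highest type and above every other type in every such plate were named. Mitochondrial genes, ribosomal protein genes, predicted genes, clone names and pseudogenes were counted and not named. Some genes that the rule names or a list holds are counted and not used here by name. Members of a gene list that are described outside this rule are named by their list.

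The lists held 419 entries in 29 lists, 0 of which were absent from the table and 5 of which were found under an older symbol. A member counted as measured with over 5 CPM in either group. A list's median log2 difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. That percentile describes these samples and is no test. The comparisons, the size rule, the lists, the rule for named genes and all but 2 alternatives were chosen before the data were examined.

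The alternatives were TMM factors from edgeR, size factors from DESeq2, equal weight for every cell, pseudocounts of 1 and 20 CPM, no minimum CPM, no minimum share of cells, and cells with at least 50000 reads and 1000 genes. Others left out each plate in turn, the cell with the largest count of each gene, or cells whose list for another class exceeded 10% of that class's own median level. The 2 added after the data were examined were a library size without ribosomal RNA and mitochondrial rows, and the removal of non-endothelial cells above 50% of the endothelial list level.

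The size rule was run on simulated cells before use. Gamma-Poisson counts were drawn for 46517 genes with the means and dispersions of capilEC and the cell numbers and depths of each comparison. In each comparison 100 genes were given an 8-fold and 100 a 32-fold difference. The rule found 66 to 97 of the former and 80 to 99 of the latter. All were set higher in the first group of the comparison, so recovery of genes higher in the second group was not measured. The changed genes were drawn only from genes expressed highly enough in capilEC to meet the minimums of the rule. The recovery therefore holds for such genes and was not measured for genes of lower level. In a simulation with no difference, the genes that met the rule are given with the counts of each comparison between groups. The counts of each type against all others were not simulated. Dispersions of capilEC stood for every type, and variation between plates or animals was not modelled. The counts from that simulation may therefore be too low. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.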

Results

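RNA was measured in single cells of microvascular fragments from adult mouse brain, sorted into 384-well plates and sequenced with Smart-seq2. The deposited table held 285,520,064 reads in 1235 cells from 4 plates, with 100021 to 854836 reads per cell and a median of 202225. The cells carried 9 type labels, which the sources used here do not spell out, and each label was deposited as 1 sample, so there were no replicates of a type. Animals were not named, so no test between types was possible, and the intervals given here cover counting error only. PCR reads without molecular identifiers are not independent molecules, so true errors are wider. How the authors assigned the labels is not given in the sources used here, and a gene used to assign a label is not independent evidence of that type.

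The label capilEC held 787 cells, 63.7% of all cells (95% exact binomial interval 61.0 to 66.4%), and 172,998,640 reads. There were 116 aEC cells (9.39%, 7.82 to 11.2%) with 31,307,636 reads, and 45 vEC cells (3.64%, 2.67 to 4.85%) with 14,114,631 reads. The smallest endothelial group was CP-EC, with 17 cells (1.38%, 0.804 to 2.19%) and 3,309,445 reads. Among the mural labels, PC held 54 cells (4.37%, 3.30 to 5.67%) and 10,701,951 reads. The label aSMC held 41 cells (3.32%, 2.39 to 4.48%) and 11,629,056 reads, and vSMC held 29 cells (2.35%, 1.58 to 3.36%) and 6,293,852 reads. FB was the smallest group, with 9 cells (0.729%, 0.334 to 1.38%) and 2,556,671 reads, and MG held 137 cells (11.1%, 9.40 to 12.98%) and 32,608,182 reads. Median reads per cell ran from 158325 in PC to 269635 in aSMC. After thinning to 100000 reads per cell, the median number of genes with a read ran from 2693 in MG to 3270 in vEC. The 3 reads that set the detection limit correspond to 0.0173 CPM in capilEC and 1.17 CPM in FB, where CPM is counts per 1000000 reads of the type. The plates s169s, s480s, s482s and s483s held 322, 261, 329 and 323 cells. Plate s169s had the lowest median depth, 159000 reads per cell, and held 7 of the 116 aEC cells against 223 of the 787 capilEC cells.

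Each type was first set against all others, to see which genes marked it alone among the 9. MG stood furthest apart. In MG, Cx3cr1, the fractalkine receptor, reached 5539 CPM (exact Poisson interval 5513 to 5564), against 54.4 CPM in the next type, CP-EC. P2ry13, a purinergic receptor, reached 1773 CPM in MG against 18.7 CPM in the next type, and Il1a, which encodes interleukin-1 alpha, 1122 against 6.51 CPM in vSMC. At least 4-fold above every other type were 167 genes in MG, 58 in FB, 28 in CP-EC, 23 in aSMC, 7 in vEC, 5 in aEC, 2 in PC, 1 in vSMC and 0 in capilEC. No simulation without a difference was run for these gene counts.

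Some of these genes have known roles in vessels. The endothelial gene Plvap, whose protein forms the diaphragms of fenestrae, stood at 2223 CPM in CP-EC (2173 to 2275) and at 9.75 CPM in the next type. In vEC, Vwf, the von Willebrand factor gene, reached 1329 CPM against 237 in capilEC. Kcnj8 and Abcc9, the subunits of an ATP-sensitive potassium channel, reached 1876 and 1317 CPM in PC and 239 and 127 CPM in vSMC, the next type for both. The vSMC level of Abcc9 rests on plate s480s, at 516 CPM in 5 cells against 4.32 to 53.0 CPM on the others. Cnn1, which encodes the smooth muscle calponin, stood at 814 CPM in aSMC and at 1.51 CPM in the next type. The vSMC gene was Ephx3, an epoxide hydrolase, at 777 CPM against 185 in PC. In FB, Col1a1, a chain of type I collagen, reached 1589 CPM (1541 to 1639). Other leading genes were Stmn2, Alpl, Cdk19, Bmx and Eps8l2 in aEC, Lrg1, Lcn2, Ptgs2 and Tmem252 in vEC, and Gpihbp1, Car8, Rbp7, Ednrb and Cd300lg in CP-EC. They were Susd5, Fbxl22, Tgfb3, Itpk1 and Mical2 in aSMC, Gjb2, Slc22a6, Gjb6, Itih2 and Pdgfra in FB, and Evi2a and Pld4 in MG. Without plate s169s the counts were 3 for aEC, 0 for vSMC and 90 for FB, without s480s 89 for FB, without s482s 4 for PC, and without s483s 11 for vEC and 2 for vSMC. Without cells with markers of another class they were 9 for PC, 3 for vSMC and 548 for FB, and a pseudocount of 20 CPM gave 3 for aEC and 0 for vSMC. Without the cell with the largest count of each gene 36 genes led in aSMC, and without cells above 50% of the endothelial list level 0 led in vSMC.

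**Figure D1:**
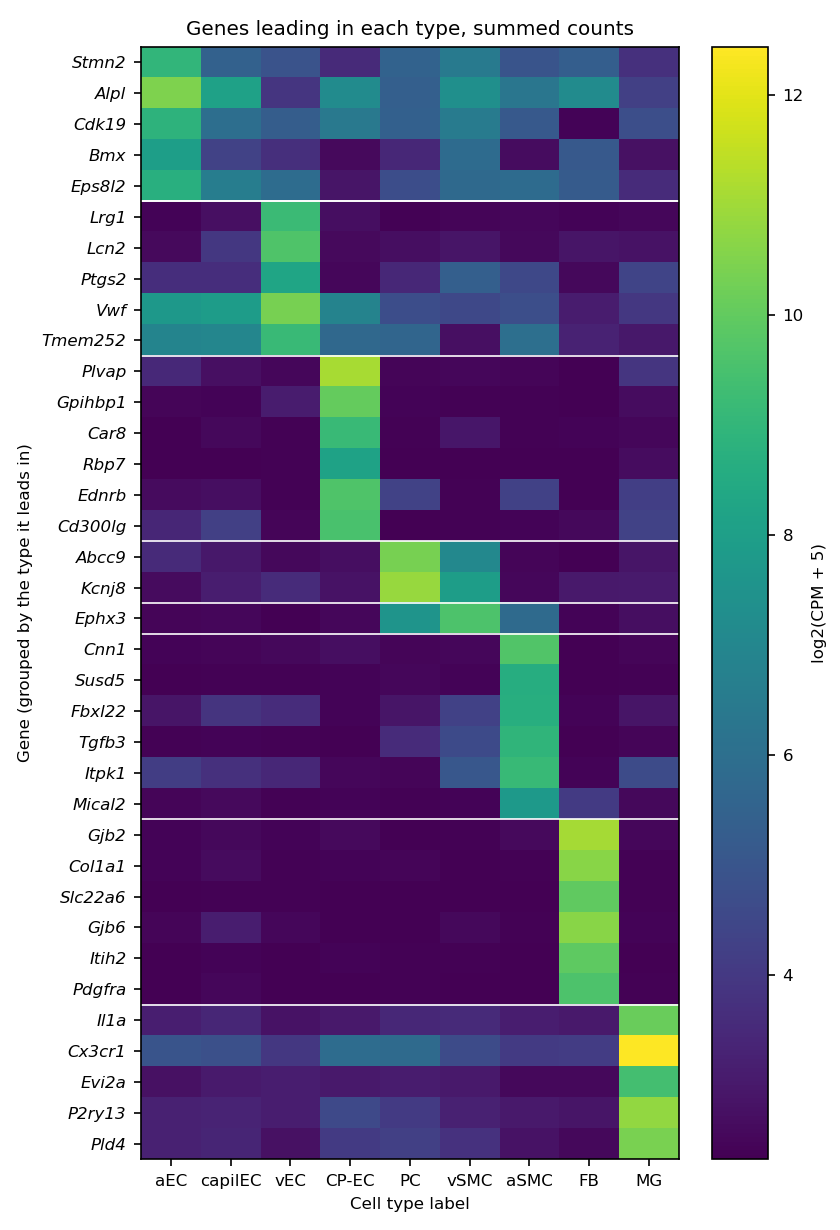
Expression of leading genes of each type, one row per gene and one column per type, coloured by log2(CPM + 5) of the summed counts of the type. The Cx3cr1 row reads 5539 CPM in MG and at most 54.4 CPM in any other type, whereas the Kcnj8 row is high in PC (1876 CPM) and intermediate in vSMC (239 CPM).

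Transcripts of other cell types were found at lower levels in several groups. The 15 genes of the pan endothelial list summed to 23203 CPM in capilEC, 5875 in PC, 4858 in vSMC, 2029 in aSMC, 1640 in FB and 1447 in MG. The median cell held 2980.2 CPM of this list in PC, 1896 in vSMC, 1198 in aSMC and 599.5 in MG. Conversely, the 13 genes of the pan mural list summed to 27331 CPM in PC and 218 in capilEC. After thinning, a read of Pdgfrb, the receptor of platelet-derived growth factor B, was found in 83.3% of PC cells (70.7 to 92.1%), 19.6% of capilEC cells (16.9 to 22.5%) and 18.2% of MG cells (12.2 to 25.8%). MG is taken here as a type that lacks Pdgfrb, so the capilEC share is read as background. The median depths were 158325, 192941 and 232674 reads, and the Pdgfrb levels 1865, 3.90 and 3.77 CPM. Without the minimum of 50% of cells with a read, every count below grew by over 1.5-fold, as from 17 to 65 genes for aEC over capilEC, so the counts hold for genes seen in most cells.

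Endothelial cells line the vessel and mural cells surround it, and the labels were grouped by their letters to compare the pair. The mean of aEC, capilEC and vEC was set against the mean of PC, aSMC and vSMC. Endothelial cells held more mRNA for Vwf (589.8 against 20.3 CPM, log2 difference 4.56), for the guidance receptor gene Robo4 (485 against 31.6, 3.74) and for Slc38a5, a glutamine transporter (946 against 34.4, 4.59). The Slc38a5 mean rests on vEC and capilEC, at 2026 and 764 CPM, and aEC stood at 47.4 CPM beside 49.7 in PC. Mural cells held more mRNA for Rgs4, a regulator of G protein signalling (4.295 in endothelial against 1501 CPM in mural cells, log2 difference −7.34), for the endothelin receptor gene Ednra (1.34 against 788, −6.97) and for Gucy1a3, a subunit of the nitric oxide receptor (3.47 against 937, −6.80). Of 227 genes at least 4-fold higher in endothelial cells, 225 had the same direction in all 4 plates, as did all 143 higher in mural cells. A gene without a difference, and not picked by its pooled value, has the same sign in 4 plates with a chance of 12.5%. The genes counted here were picked by a pooled value that the plates make up, so that chance does not apply to them. The plates describe the pooled value and do not test it.

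Of the 15 measured pan endothelial genes, 10 were at least 4-fold higher in endothelial cells (median log2 difference 2.54, plates 2.07 to 2.75). They included Pecam1, an adhesion molecule (1196 against 161 CPM), the claudin gene Cldn5 (3854 against 629) and Tek, the angiopoietin receptor (731 against 103). Of the 13 pan mural genes, 11 were at least 4-fold lower (median −6.22, plates −7.21 to −5.33), with Pdgfrb at 7.67 against 1215 CPM and Rgs5 at 109 against 4901 CPM. Both medians lay at an end of their random lists, at percentile 100 and 0. Other genes named by rank and higher in endothelial cells were Sema7a, Hs3st1, Shroom4, Gbp3, Slc35f2, Paqr5, Sema6a and Stmn1, with log2 differences of 3.38 to 4.04. Higher in mural cells were Cd248, Tagln, P2ry14, Serping1, Tpm2, Heyl, Parm1 and Atp1b2, with log2 differences of −6.82 to −6.67. The astrocyte list summed to 2777 CPM in PC, 2693 in vSMC, 578 in aSMC and 195 in capilEC.

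Of 28 measured ligands, receptors and regulators of vascular growth factor signalling, 8 were higher in endothelial cells and 3 in mural cells (median 0.62, percentile 99.9, plates 0.54 to 0.90). The receptor genes Kdr (515 against 48.5 CPM), Flt1 (2289 against 359) and Acvrl1 (459 against 75.2) were higher in endothelial cells. On plate s169s, Acvrl1 was 2.09 log2 units lower in capilEC than on the other plates. Pdgfrb, Ackr3, a scavenger receptor of CXCL12 (208 against 854), and Pdgfa (42.0 against 320) were higher in mural cells. Angpt1, the ligand of Tek, stood at 3.45 against 121 CPM and did not meet the minimum share of cells. Of 16 basement membrane genes, Fn1, the fibronectin gene, was higher in endothelial cells (743 against 162 CPM) and the laminin gene Lamc1 in mural cells (51.2 against 251). Their median was −0.67 (percentile 0.1, plates −1.01 to −0.30). Simulated cells with no difference gave 0 genes in either direction. DESeq2 factors shifted all genes by −0.21 log2 units, and leaving out cells with markers of another class raised the endothelial count to 366.

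Cells labelled aEC and capilEC were compared to see which genes set these labels apart. The aEC cells held more mRNA for Mgp, an inhibitor of calcification (429.991 against 21.2 CPM, log2 difference 4.05), for the tyrosine kinase gene Bmx (248 against 15.03, 3.66) and for Gkn3, a gastrokine (535 against 43.0, 3.49). The counting intervals were 242 to 253 CPM for Bmx in aEC and 14.5 to 15.6 in capilEC. The capilEC cells held more mRNA for the transporters Slc38a5 (47.4 against 764 CPM, −3.87) and Slc16a1, which carries lactate (172 against 1048, −2.57), and for Car4, a membrane carbonic anhydrase (205 against 1646, −2.98). In all, 17 genes were at least 4-fold higher in aEC and 11 in capilEC.

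Of the 18 measured genes of the arterial list, 4 met the size rule, all higher in aEC (median log2 difference 1.94, percentile 100, plates 1.28 to 2.19). They were Bmx, Gkn3, Mgp and the connexin gene Gja4 (162 against 20.1 CPM). Vegfc, a lymphatic growth factor (207 against 13.9 CPM), and Fbln5, an elastic fibre gene (101 against 0.988), were read in fewer than 50% of aEC cells, and their log2 differences ran over plates from −2.18 to 4.65 and from −0.67 to 4.61. Of the 12 capillary genes, 4 were at least 4-fold lower in aEC, namely Slc16a1, Car4, Ivns1abp and Hmcn1 (list median −1.68, percentile 0, plates −2.17 to −1.09). Cxcl12, a chemokine of the same list, was alike in both at 3390 and 3621 CPM. The 14 notch signalling genes leaned towards aEC with a median of 0.46 (percentile 99.8, plates 0.04 to 0.55), and none met the size rule. The notch target Hey1 stood at 251 against 85.5 CPM, Hey2 lay 1.80 log2 units higher in aEC (plates −0.0673 to 2.67), and Notch1 stood at 617 against 549 CPM. Plate s169s, which held few aEC cells, read lower for Notch1 in capilEC by −3.31 log2 units.

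Most genes of the blood-brain barrier list lay within 4-fold in aEC and capilEC. Of 19, Slc16a1 alone met the size rule, and the median was −0.50 (percentile 0, plates −0.46 to −0.10, all nearer 0 than the pooled value). The glucose transporter gene Slc2a1 stood at 3860 against 3573 CPM and Cldn5 at 3868 against 4425 CPM. Slc22a8, an organic anion transporter gene, differed by −1.91 log2 units (378 against 1435 CPM). Higher in aEC were also Stmn2, Egfl8, Cdk19, Mylk, Alpl (1414 against 271 CPM), Ssfa2, Ccnd2 and the immediate early genes Nr4a1 (457 against 67.5 CPM) and Egr1 (562 against 111). The dissociation response list, to which Nr4a1 and Egr1 belong, summed to 7793 CPM in aEC and 4326 in capilEC. Other genes higher in capilEC were Rnase4, Ndnf, Cpe, Ttyh2, Tmsb10 and Apcdd1, an inhibitor of Wnt signalling (68.6 against 337 CPM). Apcdd1 was lower on plate s169s by −3.04 log2 units in capilEC. The direction was the same in all 4 plates for 15 of the 17 genes and for all 11. Cells simulated without a difference gave 0 genes. With a pseudocount of 20 CPM, 11 genes were at least 4-fold higher in aEC.

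**Figure D2:**
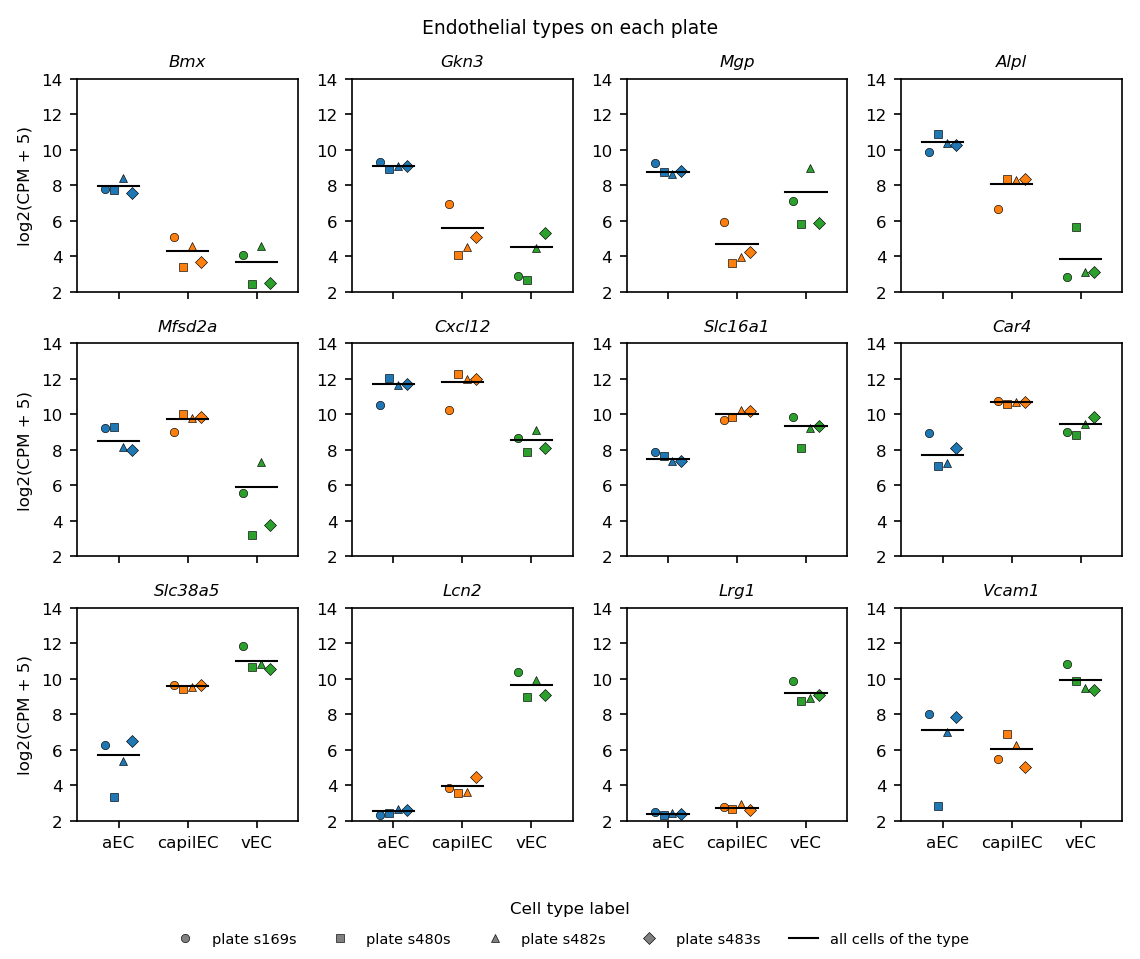
Levels of 12 genes in aEC, capilEC and vEC, as log2(CPM + 5) of summed counts on the vertical axis, with a point for each plate and a line for all cells of the type. The lines for Bmx stand at 248, 15.03 and 8.01 CPM, and those for Lcn2 at 0.926, 10.6 and 809.8 CPM.

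In vEC against capilEC, the question was which genes set the label vEC apart. The vEC cells held more mRNA for Lrg1, a secreted glycoprotein (591 against 1.66 CPM, log2 difference 6.48), for Lcn2, which binds bacterial siderophores (809.8 against 10.6, 5.71), and for Ptgs2, an enzyme of prostaglandin synthesis (302 against 7.50, 4.62). Vcam1, which leukocytes bind, was also higher (956 against 62.0, 3.84). The capilEC cells held more mRNA for Stra6, the receptor of retinol-binding protein (7.23 against 439, −5.18), and for Mfsd2a, a transporter of docosahexaenoic acid (55.7 against 851, −3.82). Cxcl12 was the most abundant of the genes named (371 against 3621, −3.27). Stra6 was lower on plate s169s by −3.76 log2 units in capilEC. The intervals were 579 to 604 CPM for Lrg1 in vEC and 1.48 to 1.87 in capilEC. The dissociation response list summed to 8554 CPM in vEC and 4326 in capilEC. At least 4-fold higher were 35 genes in vEC and 25 in capilEC, all with the same direction in 4 plates.

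Of the 16 venous genes, 8 were at least 4-fold higher in vEC (median 2.52, percentile 100, plates 2.05 to 2.97). They included Nr2f2, a nuclear receptor of venous identity (130 against 17.5 CPM), Vwf (1329 against 237) and Il1r1, the interleukin-1 receptor (273 against 40.7). Ackr1, a chemokine-binding protein of venules, stood at 481 against 1.60 CPM and was read in fewer than 50% of vEC cells. Of the 12 capillary genes, 6 were at least 4-fold lower, among them Mfsd2a, Rgcc, Spock2 and Cxcl12 (median −1.94, percentile 0, plates −2.01 to −1.80). Of the 19 barrier genes, Mfsd2a alone met the rule (median −0.49, percentile 0.07, plates −1.09 to −0.53). The thyroid hormone transporter gene Slco1c1 differed by −1.43 log2 units (689 against 1862 CPM).

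The 14 interferon response genes had a median of 0.22 (percentile 75.7, plates 0.05 to 0.23) and none met the size rule. Within that list Ifi27l2a was 2.01 log2 units higher and Irf7 1.55 units lower in vEC. Other genes named by rank and higher in vEC were Ifitm1, Gpr182, Adh1, Myof, Nrp2 and the class I genes H2-Q6 and H2-Q7. The reads of H2-Q6 and H2-Q7, near-identical genes, cannot be fully told apart, nor can those of Akap2 and Pakap. Higher in capilEC were Alpl, Slc1a1, a glutamate transporter gene (17.2 against 385 CPM), Ivns1abp, Rapgef4, Rgcc, Akap2, Pakap and Efr3b, with log2 differences of −4.24 to −2.24. A simulation with no difference gave 2 genes for vEC and 3 for capilEC. TMM factors shifted all genes by −0.20 log2 units. The count in capilEC was 12 with a pseudocount of 20 CPM and 47 without the cell with the largest count of each gene.

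The labels aEC and vEC were compared directly, and differed in more genes than either did from capilEC. In aEC, Alpl, the tissue-nonspecific alkaline phosphatase gene, stood at 1414 CPM against 9.64 in vEC (log2 difference 6.60), and Ccnd2, a cyclin gene, at 263 against 1.20 (5.43). In vEC, Lcn2 reached 809.8 CPM against 0.926 in aEC (−7.10), and Adh1, an alcohol dehydrogenase gene, 733 against 7.83 (−5.85). Slc38a5 stood at 47.4 CPM in aEC, 764 in capilEC and 2026 in vEC. In aEC 61 genes were at least 4-fold higher, and in vEC 54. In capilEC the level lay between those of aEC and vEC for 52 of the 61 genes (85.2%) and for 44 of the 54 (81.5%). These genes were picked for a gap between aEC and vEC, which by itself favours a value in between. The shares therefore do not show that capilEC is intermediate.

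Of the 18 arterial genes, 6 were at least 4-fold higher in aEC (median 2.66, percentile 100, plates 1.76 to 3.14). These included Gja4 (162 against 1.98 CPM), Unc5b, a netrin receptor gene (197 against 3.68), and Edn1, the endothelin-1 gene (623 against 114). Of the 16 venous genes, 10 were at least 4-fold lower (median −3.20, percentile 0, plates −3.71 to −2.88), with Nr2f2 at 7.83 against 130 CPM and Vwf at 203 against 1329 CPM. Among the 14 notch genes, Hey1 met the rule (251 against 14.2 CPM), and the median was 1.26 (percentile 100, plates 0.19 to 1.58). The ligand gene Jag2 (146 against 13.96 CPM) and the receptor gene Notch4 (120.1 against 19.1) lay in the same direction. Higher in aEC by rank were also Rad54b, Egfl8, Htra1, Gkn3, Bmx, Stmn2, Unc119b and Cdk19. Higher in vEC were Lrg1, Gpr182, Rnase4, Il1r1, Ptgs2, Ang, Ctsc, Ifitm1 and Fmo2, with log2 differences of −6.81 to −3.93. The direction was the same in all 4 plates for 56 of the 61 and 52 of the 54 genes. Simulated cells with no difference gave 5 genes for aEC and 3 for vEC. TMM factors shifted all genes by 0.19 log2 units.

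CP-EC cells were compared with the mean of aEC, capilEC and vEC to see how they depart from the other endothelium. CP-EC held more mRNA for Plvap (2223 against 2.86 CPM, log2 difference 8.15), for Gpihbp1, which anchors lipoprotein lipase to capillaries (1061 against 1.497, 7.36), and for the endothelin receptor gene Ednrb (799 against 0.930, 7.08). They held less mRNA for Glul, glutamine synthetase (16.0 against 959.5, −5.52) and for Plat, tissue plasminogen activator (3.63 against 356, −5.39). At least 4-fold higher were 62 genes, and 229 were at least 4-fold lower.

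Of the 10 fenestrated endothelial genes, 9 were at least 4-fold higher in CP-EC (median 5.04, percentile 100). Among them, Kdr, the main receptor of vascular endothelial growth factor, stood at 2374 against 515 CPM, its coreceptor gene Nrp1 at 1289 against 211 and Ppap2b at 857 against 21.5. Esm1, the remaining member, stood at 990 against 0.207 CPM and was read in fewer than 50% of CP-EC cells. Of the 19 barrier genes, 14 were at least 4-fold lower and none higher (median −2.71, percentile 0). In CP-EC 1 cell held 45.9% of the reads of this list, and the median cell held 1611 CPM against 4238 CPM in the summed counts. The CP-EC levels of barrier genes thus rest in part on that cell, which the counting intervals do not cover. Slc2a1 stood at 346 against 3206 CPM, with a counting interval of 326 to 367 in CP-EC. Cldn5 stood at 810.1 against 3854, the efflux pump gene Abcb1a at 76.4 against 827 and the transferrin receptor gene Tfrc at 21.5 against 407. The amino acid transporter genes Slc7a5 and Slc3a2 differed by −0.38 and −0.57 log2 units.

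Of the 18 endothelial Wnt signalling genes, 8 were at least 4-fold lower (median −3.43, percentile 0). The transcription factor genes Lef1 (6.04 against 339.8 CPM) and Foxq1 (3.02 against 268) and the inhibitor gene Apcdd1 (12.99 against 170) were among them. Fzd4 and Tspan12, parts of the norrin receptor, lay the other way, at 113 against 44.6 and 569 against 164 CPM. Other genes named by rank and higher in CP-EC were Car8, Fam167b, Cd300lg, Slc43a3, Rbp7, Tnfaip2, Cd24a, Jam3 and Igfbp3. Lower were Mal, Lamb2, Degs2, Far2, Net1, Tgfb2, Sgpp2, Vcam1 and Ctsc. The means of Vcam1 and Ctsc rest largely on vEC, where they stood at 956 and 830.1 CPM against 62.0 and 166 in capilEC. Net1 had 3 reads in CP-EC, a ratio of 254 with a counting interval of 86.9 to 1232.

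Plate s483s, the only plate with at least 5 CP-EC cells, held 10 of the 17 and gave list medians of 5.89, −3.61 and −3.62 for fenestrated, barrier and Wnt genes. Without it the counts were 137 and 427 genes. They were 96 genes higher with DESeq2 factors, which shifted all genes by 0.31 log2 units, and 472 lower without the cell with the largest count of each gene. Cells simulated without a difference gave 12 and 63 genes.

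**Figure D3:**
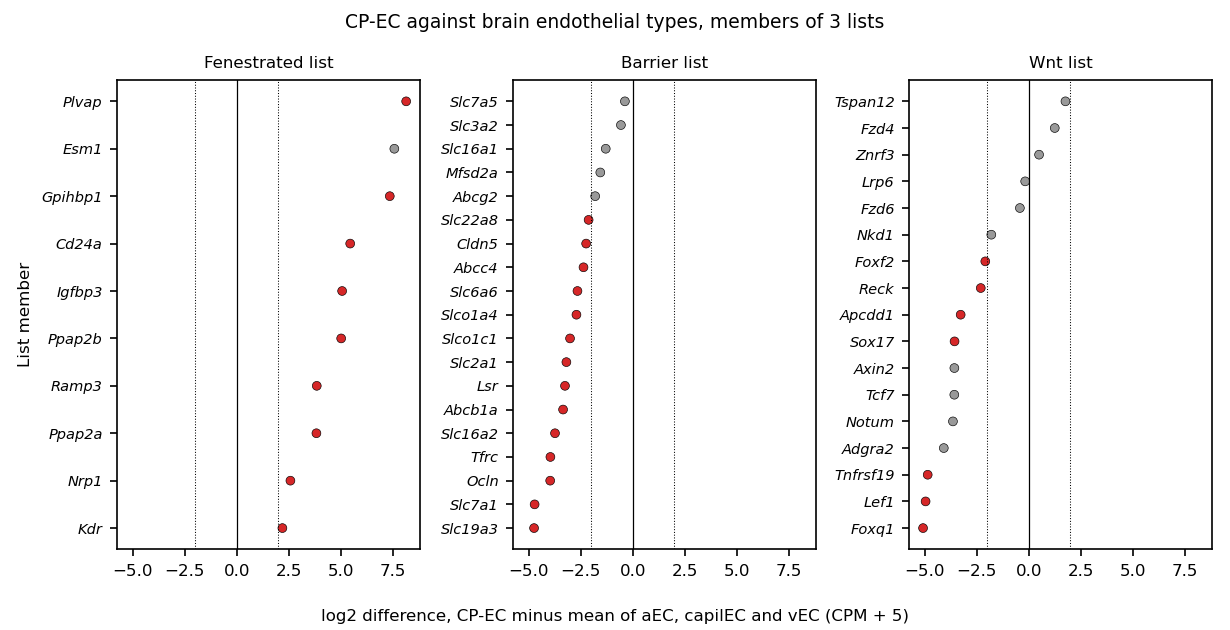
Log2 difference of CP-EC minus the mean of aEC, capilEC and vEC on the horizontal axis for genes of the fenestrated, barrier and Wnt lists, with red points for genes that met the size rule, grey for the others and dotted lines at a 4-fold difference. Of the fenestrated genes 9 of 10 are red and to the right, and of the barrier genes 14 of 19 are red and to the left.

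PC and aSMC cells were compared to see which genes part these mural labels. PC cells held more mRNA for Kcnj8 (1876 against 0.688 CPM, log2 difference 8.37), for Abcc9 (1317 against 0.516, 7.90) and for Atp13a5, a transport ATPase gene (642 against 0.688, 6.83). The aSMC cells held more mRNA for the contractile genes Cnn1 (0.467 against 814, −7.23) and Pln, a regulator of the calcium pump (7.66 against 1707, −7.08), and for Myocd, a coactivator of smooth muscle genes (1.21 against 789, −7.00). The counting intervals for Kcnj8 were 1851 to 1903 CPM in PC and 0.297 to 1.355 in aSMC. At least 4-fold higher were 154 genes in PC and 150 in aSMC. Of the 154, 71 (46.1%) were higher still in capilEC, and the pan endothelial list summed to 5875 CPM in PC and 2029 in aSMC. The dissociation response list summed to 20127 CPM in aSMC and 6757 in PC.

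Of the 16 pericyte genes, 9 were at least 4-fold higher in PC (median 4.36, percentile 100, plates 3.41 to 5.75), including Vtn, the vitronectin gene (7339 against 339 CPM). Of the 20 contractile genes, 15 were at least 4-fold lower (median −3.61, percentile 0, plates −5.14 to −2.82). Acta2, smooth muscle actin, stood at 257 against 6440.1 CPM, the myosin heavy chain gene Myh11 at 44.1 against 2419.8 and Tagln at 63.1 against 2738. The myosin light chain gene Myl9 stood closer, at 2997 against 4565 CPM. Of the 25 channels and receptors of vascular tone, Kcnj8 and Abcc9 were higher in PC and Pde3a, a phosphodiesterase gene, was lower (195 against 811 CPM). The endothelin receptor gene Ednra stood at 794 against 723 CPM and Gucy1a3 at 816 against 1063. The median of the tone list was 0.13 (percentile 65.9, plates 0.00 to 0.47), and it was −0.0384 with TMM factors and −0.19 without plate s482s.

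Higher in PC by rank were also Ifitm1, Slc6a20a, Plxdc2, Art3, Ptn, Lrrc8b, Trf and Adk, with log2 differences of 4.52 to 5.85. Higher in aSMC were Ltbp1 (1.78 against 1116 CPM), which binds latent transforming growth factor beta, and Pdlim3, Gpr20, Palld, Itpk1, Adamtsl1, Susd5, Tspan2 and Fbxl22. Palld had 3 reads in PC, a ratio of 1960 with an interval of 671 to 9502, and Adamtsl1 had 2. The direction was the same in 4 plates for 127 of the 154 and 139 of the 150 genes. Trf differed by less than 2-fold on at least 1 plate. A simulation with no difference gave 7 genes for PC and 10 for aSMC. TMM and DESeq2 factors shifted all genes by −0.17 and −0.13 log2 units. A pseudocount of 20 CPM gave 98 genes for PC, and leaving out cells with markers of another class, which kept 12 of 54 PC cells, gave 376 for aSMC.

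**Figure D4:**
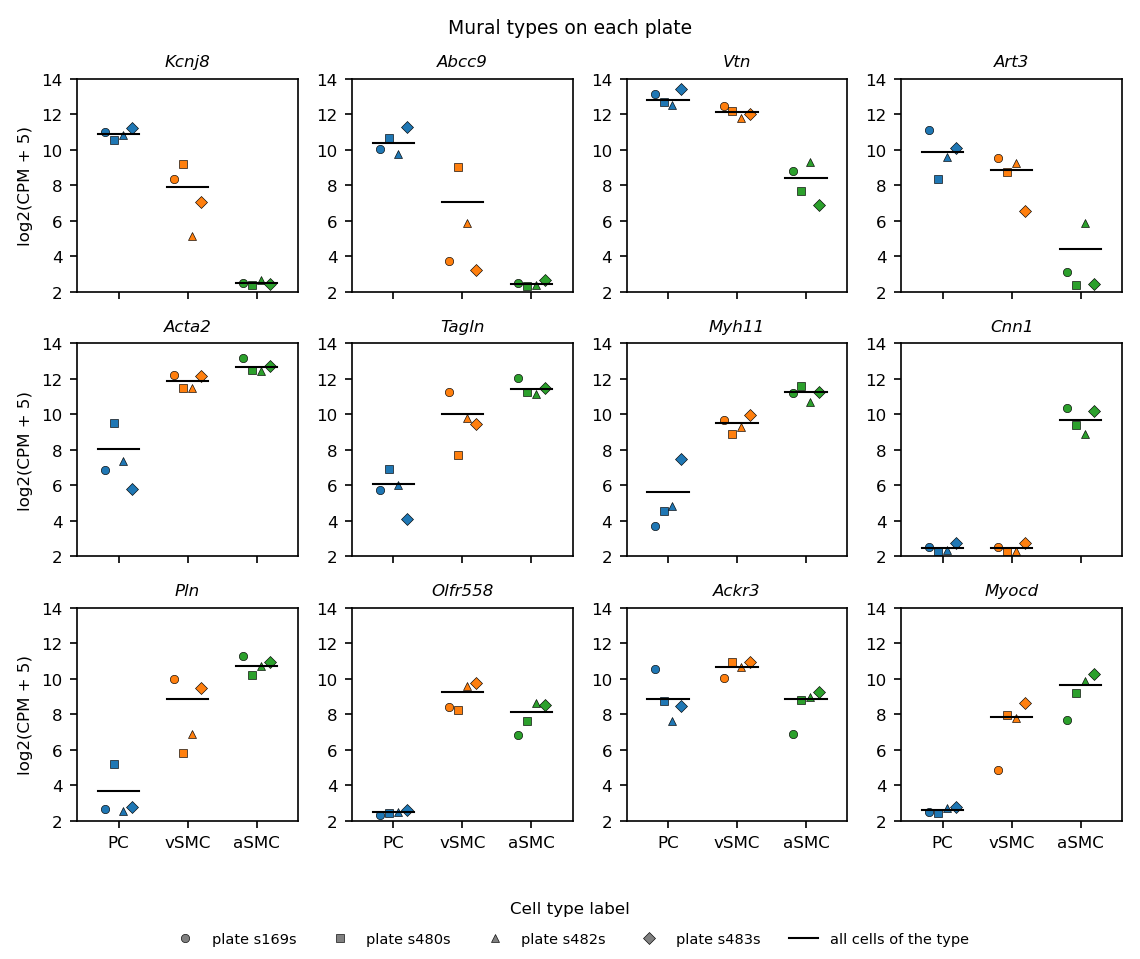
Levels of 12 genes in PC, vSMC and aSMC, as log2(CPM + 5) of summed counts on the vertical axis, with a point for each plate and a line for all cells of the type. The lines for Acta2 stand at 257, 3728 and 6440.1 CPM, whereas those for Cnn1 stand at 0.467, 0.636 and 814 CPM.

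In vSMC against aSMC, the question was how the SMC labels differ. The aSMC cells held more mRNA for Cnn1 (0.636 against 814 CPM, log2 difference −7.18), for Csrp1, a cytoskeletal LIM protein gene (66.6 against 2334, −5.03), and for Errfi1, an inhibitor of the epidermal growth factor receptor (18.9 against 1176, −5.63). The vSMC cells held more mRNA for the pericyte genes Atp13a5 (352 against 0.688, 5.97) and Art3 (469.7 against 16.4, 4.47). Acta2 was abundant in both, at 3728 against 6440.1 CPM. In vSMC 126 genes were at least 4-fold higher, and in aSMC 101. Of the 126, 63 (50%) were higher still in capilEC, and the pan endothelial list summed to 4858 CPM in vSMC and 2029 in aSMC. The dissociation response list summed to 4514 and 20127 CPM.

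Of the 20 contractile genes, 4 were at least 4-fold lower in vSMC, namely Cnn1, Lmod1 (136 against 679.9 CPM), Smtn (99.1 against 1069) and Synpo2 (median −1.55, percentile 0, plates −2.21 to −1.27). Smtn, which encodes smoothelin, was also lower on plate s169s by −2.56 log2 units in capilEC. Of the 15 pericyte genes, 7 were at least 4-fold higher in vSMC (median 3.10, percentile 100, plates 2.24 to 3.64), with Vtn at 4492 against 339 CPM and Higd1b at 1001 against 225. None of the 25 tone genes met the rule (median 0.13, percentile 64.4, plates −0.03 to 0.13). The chloride channel gene Ano1 stood at 821 against 248 CPM and Ptger3, a prostaglandin receptor gene, at 144 against 35.3. That median was −0.0246 with no minimum CPM, −0.0509 without cells with markers of another class and −0.15 without plate s483s.

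The levels in vSMC lay between those of PC and aSMC for 131 of the 154 genes higher in PC than in aSMC (85.1%) and for 117 of the 150 higher in aSMC (78%). These genes were picked for a gap between PC and aSMC, which by itself favours a value in between. Higher in vSMC than in aSMC by rank were also Tnfrsf21, Iars2, Plxdc2, Ggt5, Lrrc8b, Ifitm1, Slc6a20a and Ocln, with log2 differences of 4.02 to 5.02. On at least 1 plate Plxdc2 and Ocln differed by less than 2-fold, as did Ehd1 and Prkcd in the other direction. Trf, the transferrin gene, met the rule as well (158 against 2.75 CPM, 4.40), but 1 cell held 95.8% of its vSMC reads. Without that cell the Trf difference was 0.65, and without plate s169s 0.47. Higher in aSMC were Susd5, Mical2, Tspan9, Ehd1, Trp53i11, Nexn, Prkcd and Usp2, with Susd5 and Mical2 at 2 reads each in vSMC. The ratio for Susd5 was 1236 (counting interval 342 to 10203). The direction was the same in 4 plates for 89 of the 126 and 94 of the 101 genes. Simulated cells with no difference gave 28 genes for vSMC and 35 for aSMC, and TMM factors shifted all genes by −0.12 log2 units. A pseudocount of 20 CPM gave 69 genes for vSMC, and leaving out plate s480s gave 199. The count for aSMC was 241 without cells with markers of another class, 193 without the cell with the largest count of each gene and 155 without plate s483s.

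In vSMC against PC, cells of neighbouring mural labels were compared. The vSMC cells held more mRNA for the contractile genes Acta2 (3728 against 257 CPM, log2 difference 3.83), Myh11 (726 against 44.1, 3.90) and Tagln (1029 against 63.1, 3.93). They also held more mRNA for Olfr558, an olfactory receptor gene (607 against 0.561, 6.78), which stood at 279.9 CPM in aSMC. PC cells held more mRNA for Abcc9 (127 against 1317, −3.32, plates −8.05 to −1.67) and for Uchl1, a deubiquitinating enzyme gene (15.7 against 386, −4.24). At least 4-fold higher were 33 genes in vSMC and 49 in PC. The pan endothelial list was close in these types, at 4858 and 5875 CPM.

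Of the 18 contractile genes, 7 were at least 4-fold higher in vSMC (median 1.82, percentile 100, plates 0.62 to 2.77), among them Pln (455 against 7.66 CPM) and Tpm2 (1565 against 310). Of the 16 pericyte genes, 2 were at least 4-fold lower, Abcc9 and Kcnj8 (239 against 1876 CPM), with a list median of −0.78 (percentile 0, plates −1.46 to −0.46). The same pair was lower among the 24 tone genes, whose median was 0.21 (percentile 83.5, plates −0.28 to 0.10). Ptger3 stood at 144 CPM in vSMC and had 1 read in PC (0.0934 CPM, counting interval 0.00237 to 0.521). Agtr1a, an angiotensin receptor gene, had 0 reads in vSMC, which allows up to 0.477 CPM, against 52.9 CPM in PC.

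Higher in vSMC by rank were also Nrip2, Sncg, Atxn7l1, Pgf, which encodes placental growth factor (625 against 40.2 CPM), Ric8, Elk3 and Rcan2. Higher in PC were Sf3b3, Smox, Inip, St8sia4, Rgl1, Tmem173, Csk, Olfml3, Itih5 and Stra6, with log2 differences of −4.79 to −3.20. Of the 49 genes higher in PC, 21 (42.9%) were higher still in capilEC, such as Itih5 (852 CPM in capilEC against 246 in PC) and Stra6 (439 against 77.6). Olfml3 and Tmem173 stood higher still in MG, at 2872 and 1024 CPM. The direction was the same in 4 plates for 22 of the 33 and 37 of the 49 genes. Of the genes named, Pln, Tagln, Atxn7l1, Elk3, Smox, Inip, St8sia4, Rgl1, Tmem173 and Stra6 differed by less than 2-fold on at least 1 plate. Cells simulated without a difference gave 19 genes for vSMC and 29 for PC, more than 50% of each count. Leaving out plates s169s, s480s or s482s gave 61, 62 and 115 genes for vSMC, and leaving out s482s or s483s gave 85 and 112 for PC. The counts were 280 and 235 without cells with markers of another class, 52 and 75 with equal weight for every cell, and 21 and 32 with a pseudocount of 20 CPM. Without the cell with the largest count of each gene, 92 genes were higher in PC, and without cells above 50% of the endothelial list level, 88 were higher in vSMC.

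The 9 FB cells were compared with the mean of PC, aSMC and vSMC to see which genes part FB from mural cells. FB held more mRNA for Col1a1 (1589 against 0.213 CPM, log2 difference 8.26), for Pdgfra, the receptor of platelet-derived growth factor A (782 against 0.0623, 7.28), and for the connexin genes Gjb2 (2150.5 against 0.368, 8.65) and Gjb6 (1573 against 0.351, 8.204). Transporters were also higher, such as Slc7a11, which exchanges cystine for glutamate (2351 against 2.07, 8.38), and Slc22a6, which carries organic anions (983 against 0.0287, 7.62). Mural cells held more mRNA for Mcam, an adhesion molecule (0.782 against 1128, −7.61), for Rgs5 (32.1 against 4901, −7.05) and for Myh11 (1.96 against 1063, −7.26). At least 4-fold higher were 211 genes in FB and 344 in mural cells.

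Of the 16 measured fibroblast genes, 11 were at least 4-fold higher in FB (median 5.46, percentile 100), with the proteoglycan genes Dcn (3709 against 59.3 CPM) and Lum (1525 against 10.2) among them. Of the 13 pan mural genes, 9 were at least 4-fold lower (median −6.45, percentile 0, and −6.30 with genes without a read set to the limit). Vtn, of the same list, was as high in FB as in mural cells (4760.1 against 4057 CPM). Of the 31 growth factor genes, 4 were higher in FB and 4 lower (median −0.61, percentile 1.14). Higher were Pdgfra, Tgfbr1 (169.4 against 28.5 CPM), Igf2 (2748 against 212) and Edn3 (717 against 38.7), and lower were Pdgfa (1.17 against 320), Tek, Flt1 and Ackr3 (46.2 against 854). Tek and Flt1 belong to the pan endothelial list, which summed to 1640 CPM in FB, 5875 in PC, 4858 in vSMC and 2029 in aSMC. Of the 17 basement membrane genes, the laminin gene Lamb1 was higher in FB (663 against 72.2 CPM) and Agrn, the agrin gene, lower (45.4 against 215). The median of that list was −0.05 (percentile 30.7), and it was 0.33, 0.12 and 0.03 without plates s169s, s480s and s482s, −0.57 without s483s, 0.19 with DESeq2 factors and 0.17 with equal weight for every cell.

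Higher in FB by rank were also Slc1a3, a glutamate transporter gene, Efemp1, Serpinf1, Itih2, Nnat and Aldh1a2, an enzyme of retinoic acid synthesis (1373 against 2.60 CPM). Lower were Gucy1a3, Rgs4, Gja4, Gper1, Des, Bcam, Higd1b, Gucy1b3 and Aspn. Gucy1a3 had 0 reads in FB, against a mural mean of 937 CPM. The limit of 3 counts (1.17 CPM) makes it 798-fold lower, and the upper end of the counting interval at least 649-fold. Mcam had 2 reads, a ratio of 1442 with a counting interval of 399 to 11903. No plate held 5 FB cells, so no values by plate were computed, and simulated cells with no difference gave 84 genes for FB and 180 for mural cells. DESeq2 factors shifted all genes by 0.22 log2 units. Leaving out plate s480s gave 348 genes for FB, and leaving out the cell with the largest count of each gene gave 530 for mural cells. Without cells with markers of another class, 1 FB cell was left, the counts were 1059 and 836, and the differences of Gjb2, Gjb6, Slc1a3, Slc22a6, Aldh1a2 and Nnat were −0.11, −0.16, −0.18, −0.0101, −0.0598 and −0.0454.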

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

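The tests on endothelial transcripts in PC and on the levels in vSMC were chosen only after their results were seen, and the 3 tests on plate s169s were written before.

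Signals outside the comparisons are given first. On plate s480s Xist, the RNA of the inactive X chromosome, stood at 715 CPM, against at most 0.323 CPM on the other plates. The other signals are genes of lists for other cells with at least 50 CPM and 200 reads in a type of more than 10 cells, where 1 cell held over 85% of the reads. In CP-EC, Mbp, a myelin gene, stood at 148 CPM with 100% of its reads in 1 cell. The water channel gene Aqp1 stood at 135 CPM in CP-EC, with 99.6% of its reads in 1 cell. In PC, Enpp2 stood at 439 CPM and 1 cell held 87.3% of its reads. Ttr, the transthyretin gene, stood at 194 CPM in PC, with 88.5% in 1 cell, the same cell as for Enpp2, and that cell also held over 85% of the reads of Kl (117 CPM), Kcnj13 (75.5 CPM) and Folr1 (71.4 CPM). In vEC, the class II genes Cd74 and H2-Aa stood at 110.1 and 75.3 CPM, with 86.1% and 91.6% of their reads in 1 cell, which also held 92.1% of those of H2-Ab1 (64.8 CPM). From the list of other leukocytes, that vEC cell held 99.4% of the reads of Ms4a1 (24.2 CPM) and 62.5% of those of Cd79a (97.1 CPM). In vSMC, Trf stood at 158 CPM, with 95.8% in 1 cell. From the perivascular macrophage list, that vSMC cell held 99.6% of the reads of Pf4 (38.5 CPM) and 99.1% of those of Cbr2 (36.4 CPM).

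The first pattern is the endothelial transcripts in PC cells, where the median pan endothelial gene stood at 19.3% of its level in capilEC. Reads spread evenly among the wells of a plate would give PC and MG cells alike levels, and the ratio of their medians of this list was 2.69 on the lowest plate and 8.18 on the highest, which argues against an even spread as the whole cause. Endothelial cells or pieces of them in the wells would bring all endothelial genes in similar proportion. In PC 10 of the 15 genes lay within 2-fold of their median ratio, between the bounds set for and against it. The bound for it also covered vSMC and was not met there, with 9 genes, while 14 lay within 2-fold in aSMC and 13 in MG. The ratios to capilEC ran from 6.25 to 56.6% in PC and from 1.21 to 52.5% in vSMC. In PC the tenth of cells with most of this list (5 cells) held 32.2% of its CPM summed over cells, so the signal was not confined to a few wells. Pieces in wells therefore remain a candidate explanation, and expression in PC itself, which the label would allow, was not tested.

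The second pattern is the levels in vSMC between PC and aSMC, in genes picked for a gap between those types. A mixture of PC and aSMC cells or RNA under this label would place aSMC genes at 1 common share of their aSMC level, yet 25% of 76 such genes lay over 4-fold from the median share of 27.3%. In 100 drawn mixtures of 8 aSMC and 21 PC cells the highest value was 9.21%. The drawn cells were among those that set the 76 genes and their aSMC levels, so these mixtures would scatter less than independent cells. Cnn1 was read in 2 of 29 vSMC cells and 29 of 41 aSMC cells, and 5 genes stood above their aSMC level. These values argue against a mixture as the whole cause only as far as the drawn cells stand for independent ones. A difference in cell type, which the labels give, stays open and was not tested.

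The third pattern is 91 genes at least 4-fold lower on plate s169s than on the other plates in capilEC, against 4 higher, among them Atxn2l (−4.15 log2 units), Sun2 (−4.14) and Notch1 (−3.31). In MG the same genes had a median difference of −2.10, with 86 of 88 below 0, which is consistent with a difference of the whole plate whatever the cell type. Their median GC content was 5.90 percentage points above that of genes matched on level (56.2% against 50.3%, with draws of 46.5 to 53.3%), which goes with a GC bias of that plate's libraries, although their transcripts were also longer (4010.0 against 2848 bases). The share that overlap another gene was 5.68 points above matched genes, within the draws, so a different counting of overlapping genes cannot be told apart from none. Genes named in the comparisons and among the 91 included Efr3b (−2.68), Sema7a (−2.64), Tspan9 (−2.58), Bcam (−2.13) and Ttyh2 (−2.10). No biological explanation was tested, since the labels give no group that follows the plates.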

How the results depend on the processing

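The alternatives without ribosomal RNA and mitochondrial rows, and without non-endothelial cells above 50% of the endothelial list level, were chosen only after the data were seen. No paired analysis was possible because each type was 1 sample and no animal was named, and the planned tests on animals were not run for that reason. Over all alternatives, 360 values of the 27 gene counts stayed within 1.5-fold and 72 moved. For the 31 list medians 400 values kept their place, 55 moved and 10 reversed, and for the 215 genes named 2719 stayed, 285 moved and 6 reversed. TMM factors, a pseudocount of 1 CPM, no minimum CPM and the library size without ribosomal RNA and mitochondrial rows moved no count. The filter at 50000 reads and 1000 genes removed no cell and says nothing. Depth and cell number limit FB and CP-EC most, with limits of 1.17 and 0.906 CPM for a count of 0. Where a value moved or reversed below, the cause was not tested, except that dropping a minimum admits more genes.

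With no minimum share of cells, genes higher in the first and second group were 65 and 23 for aEC against capilEC, 95 and 81 for vEC against capilEC, 183 and 148 for aEC against vEC, and 395 and 794 for CP-EC against brain endothelium. They were 628 and 450 for PC against aSMC, 580 and 475 for vSMC against aSMC, 416 and 533 for vSMC against PC, 873 and 1124 for FB against mural types, and 351 and 494 for endothelial against mural types. Genes above all other types were then 9 in aEC, 19 in vEC, 107 in CP-EC, 35 in PC, 62 in aSMC, 25 in vSMC, 305 in FB and 361 in MG.

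With a pseudocount of 20 CPM, 11 genes were higher in aEC than capilEC, 12 in capilEC than vEC, 98 in PC than aSMC, 69 in vSMC than aSMC, and 21 and 32 in vSMC against PC, with 3 genes leading in aEC and 0 in vSMC. DESeq2 factors gave 96 genes higher in CP-EC and a basement membrane median of 0.19 in FB against mural types (−0.05 as reported). TMM factors gave −0.0384 (0.13 as reported) for the vascular tone channels and receptors list in PC against aSMC. Equal weight for every cell gave 52 and 75 genes in vSMC against PC and a basement membrane median of 0.17 in FB. With no minimum CPM the tone median of vSMC against aSMC was −0.0246.

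Without cells with markers of another class, 376 genes were higher in aSMC than PC, 241 in aSMC than vSMC, 280 and 235 in vSMC against PC, 1059 and 836 in FB against mural types, and 366 in endothelial against mural types. The tone median of vSMC against aSMC was −0.0509, and 9 genes led in PC, 3 in vSMC and 548 in FB. This filter left 12 PC, 16 vSMC and 1 FB cells, and in that FB cell Gjb2 (−0.11), Gjb6 (−0.16), Slc1a3 (−0.18), Slc22a6 (−0.0101), Aldh1a2 (−0.0598) and Nnat (−0.0454) reversed. Most FB cells exceeded its bound for the pan mural list, which holds Vtn, so their removal does not show that they were mixed. Without non-endothelial cells above 50% of the endothelial list level, 88 genes were higher in vSMC than PC and 0 led in vSMC. Without the cell with the largest count of each gene, 47 genes were higher in capilEC than vEC, 472 in brain endothelium than CP-EC, 193 in aSMC than vSMC, 92 in PC than vSMC and 530 in mural types than FB, and 36 led in aSMC.

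Leaving out each plate in turn gave 68 to 137 and 236 to 427 genes for CP-EC (most without s483s), 116 to 199 for vSMC over aSMC (most without s480s) and 144 to 155 for aSMC over vSMC (most without s483s). It gave 47 to 115 for vSMC over PC (most without s482s), 67 to 112 for PC over vSMC (most without s483s) and 253 to 348 for FB over mural types (most without s480s). Leading genes ran from 3 to 6 in aEC, 7 to 11 in vEC, 3 to 4 in PC, 0 to 2 in vSMC and 67 to 90 in FB. The basement membrane median of FB ran from −0.57 without s483s to 0.33 without s169s, with 0.12 without s480s and 0.03 without s482s. For PC against aSMC, median of the vascular tone channels and receptors list, the range was −0.19 (without s482s) to 0.27 (without s480s). For vSMC against aSMC, median of the vascular tone channels and receptors list, it was −0.15 (without s483s) to 0.20 (without s480s).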

Other observations

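Every value in this part was looked at only as a description, and no test was run. MG held the genes of microglia at high levels, with 51515 CPM summed over the microglia list and at most 1172 CPM in any other type (CP-EC, 75.4% of the reads in 1 cell). Among them were Csf1r, the receptor of colony-stimulating factor 1 (4639 CPM), the complement gene C1qa (3245 CPM) and Tmem119 (2569 CPM). MG also held the most of the dissociation response list, whose immediate early genes respond to tissue handling and to stimulation. This list summed to 31448 CPM in MG and 20127 in aSMC, against 8554 in vEC, 7793 in aEC, 7168 in FB, 6757 in PC, 6187 in CP-EC, 4514 in vSMC and 4326 in capilEC. Egr1 stood at 4407 CPM in MG, 2479 in aSMC and 111 in capilEC, and Fos at 3442, 3838 and 386 CPM. Genes of antigen presentation by class II summed to 1898 CPM in MG, 452 CPM in PC and 314 CPM in vEC, and 1 cell held 60.0% of the reads in PC and 88.1% in vEC.

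The interferon response list summed to 6354 CPM in capilEC and 9022 in CP-EC, against 1848 in aSMC, 3043 in vSMC and 3199.8 in PC. The class I genes B2m, H2-D1 and H2-K1 and Ifitm3 held most of these sums, and not every member followed them, as Irf1 stood at 127 CPM in aEC and 151 in aSMC. The chemokine scavenger gene Ackr3 stood at 1653 CPM in vSMC, 457 in aSMC and 453 in PC. Proliferation genes summed to 452 CPM in vEC and to at most 168 CPM in the other types. In vEC 1 cell held 64.7% of the reads of that list, and the same cell held 99.4% of the reads of Top2a (34.9 CPM) and 100% of those of Mki67 (19.2 CPM), genes of dividing cells.

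Lists of cells that vascular fragments can carry along were low in most types. The neuron list summed to at most 106 CPM (vSMC, 37.5% of the reads in 1 cell), the erythrocyte list to at most 40.8 CPM (CP-EC, 65.9% in 1 cell), and the list of other leukocytes to at most 122 CPM (vEC, 69.6% in 1 cell). The perivascular macrophage list ran from 132 CPM in PC to 721 CPM in CP-EC, where Stab1 (496 CPM) and Dab2 (225 CPM) held nearly all of it and Mrc1 had 0 reads. Stab1 and Dab2 were also read in capilEC (188 and 182 CPM). The choroid plexus epithelium list reached 979 CPM in PC, where 1 cell held 92.0% of the reads and the median cell 0 CPM, 905 in FB, where 1 cell held 40.1%, and 451 in CP-EC, where 1 cell held 29.9%. The ependymal list reached 906 CPM in PC, of which Rarres2 held 744 CPM. The oligodendrocyte lineage list reached 1715 CPM in MG and 1651 in FB (34.0% of the reads in 1 cell), where Trf stood at 1518 and 1310 CPM. The astrocyte list reached 4325 CPM in FB (31.5% in 1 cell), 2777 in PC and 2693 in vSMC. The fibroblast list summed to 20681 CPM in FB and to at most 1463 CPM elsewhere (PC).

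The plates differed in genes of cell sex, which the labels do not give. On s480s Xist stood at 715 CPM and the Y-linked genes at 3.35 CPM, with Xist alone read in 193 of 261 cells, both in 63, Y-linked genes alone in 1 and neither in 4. On s169s, s482s and s483s Xist stood at 0.0176, 0.323 and 0.102 CPM and the Y-linked genes at 228, 235 and 277 CPM. The cell sex list summed to 270.3 CPM in FB and to 679 CPM in MG, the lowest and highest of the types.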
